A study of Homo sapiens with 120 samples.

How the data were processed

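The data were 120 RNA sequencing libraries from 3 human mammary epithelial cell lines, MCF7, MCF10A and MCF12A, as deposited in 1 series. MCF7 is an estrogen receptor positive breast cancer line, and MCF10A and MCF12A are non-tumorigenic mammary epithelial lines. Each line had 8 groups of 5 libraries, 1 per batch, with batches labelled 1, 2, 3, 5 and 6. Per the labels, the groups were a vehicle control (0.1% DMSO), bisphenol A (BPA) at 250 nM or 50 nM, a mixture of 7 bisphenols at 50 nM, a mixture of the 6 alternatives without BPA at 50 nM, the 7 bisphenols at 1 nM, the herbicide pendimethalin at 10 nM, and its formulation Stomp Aqua at 10 nM of pendimethalin. The 6 alternatives were BPAF, BPAP, BPB, BPF, BPS and BPZ, and exposure lasted 48 h. For the 7 bisphenols the labels listed 50 nM of BPA and 50 nM of the alternatives, or 1 nM and 1 nM at the lower dose. They did not say whether the dose of the alternatives is per compound or in total. MCF7 was grown in another medium than MCF10A and MCF12A, whose medium held EGF, hydrocortisone, cholera toxin and insulin, so line and medium could not be told apart.

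Per the submitters' processing notes, reads of 150 bp from 2 ends (NovaSeq, poly(A) RNA) were quantified with Salmon against GRCh38. The Salmon version and index were not given in the sources used here. Values were taken in the units of the deposited tables: per the file headers, the read column holds the estimated count of each transcript, the TPM column holds TPM, and the length column holds the effective length. Gene values were sums of the estimated counts as deposited over the transcripts of a gene. The deposited TPM values served only to average the effective length of a gene over its transcripts. Of 177456 transcripts, 167027 (94.1%) were matched to a gene of GENCODE v29 (GRCh38), which gave 35052 genes, 29296 of them with a read. Matched transcripts held 97.3% to 97.8% of the reads of a library. Library totals ran from 16721280 to 65795504 reads (median 28771461). No pair of replicates shared its counts: the smallest chi-square per gene between replicates was 11.3 and the median 77.5.

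Genes were tested in R 4.3.3 with edgeR 4.0.16 by quasi-likelihood F tests, in 1 fit per line with 40 libraries, TMM size factors and the default filter of edgeR, which left 14983 genes in MCF7, 14244 in MCF10A and 14196 in MCF12A. Adjusted p values are those of Benjamini and Hochberg, with a threshold of 0.05. Errors of log2 fold changes are standard errors, and levels are TMM-normalised CPM, mean ± SD over 5 libraries unless another n is given. There were 33 comparisons: 21 of an exposure with the control of its line, 9 of an exposure with another exposure, and 3 of the response of MCF7 with the mean response of MCF10A and MCF12A (30 libraries per fit). The 7 comparisons within a line share 5 controls and are not independent. The labels gave each library a batch number, the same as its replicate number, but did not state that batch was used as a covariate, so the planned fit had no batch term. The same fit with a replicate block was 1 of the alternatives. Others were DESeq2 1.42.0, RLE size factors, no low count filter, an offset for effective length, a fit of the 2 compared groups only, and leaving out each library in turn. The fit, the comparisons, the lists and these alternatives were fixed before the data were examined. After the data had been seen, the block was also combined with DESeq2, RLE size factors, no filter, the length offset and a covariate for a length trend, and was run without 2 doubted libraries, without MCF7 batch 3 and without each batch.

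There were 17 gene lists, chosen from general knowledge before the data were examined (genes listed): estrogen induced (40), estrogen repressed (12), steroid and nuclear receptors (16), proliferation (28), aryl hydrocarbon and xenobiotic response (13), oxidative stress (12), unfolded protein and integrated stress response (14), p53 response (12), cholesterol synthesis (14), glucocorticoid and androgen response (12), interferon response (12), inflammatory cytokines (14), luminal epithelial markers (12), basal epithelial markers (10), mesenchymal and fibroblast markers (12), immune cell markers (7) and mitochondrial encoded genes (13). DDX58 was found under its symbol RIGI, and TNF was not found in the annotation. Lists with fewer than 5 measured genes were not tested. Each list was tested with camera of limma 3.58.1 on log2 CPM with a fixed correlation of 0.01 between genes, adjusted over 329 tests for the comparisons with control and separately for the other 2 kinds of comparison. The same test with the correlation estimated from the data is given beside it, and fry was run as a second test. Fry tests only whether the genes of a list lean 1 way on balance. A camera call made with the fixed correlation can come from genes that vary together. Without the block, 35 list tests passed against control with the fixed correlation and 2 with the estimated correlation. With the block, 58 and 0 passed. Fry passed in 0 of these tests without the block and in 6 with it. In every list that passed, the median had the sign of the test.

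Genes were named by a fixed rule. It took genes with an adjusted p below 0.05, a mean of at least 1 CPM in the higher group, a symbol, and the same direction in at least 4 of 5 batches, by size of change: up to 12 each way for BPA at 250 nM in MCF7, 6 for other exposures and 3 for the rest. Where the block called over 1.5 times as many genes, the same rule was applied to the blocked fit for up to 3 each way. Of each list, 2 to 6 genes past the threshold over the list alone were named, and GREB1, PGR, TFF1, PDZK1, CXCL12, MKI67 and ESR1, chosen beforehand, were given in every case in MCF7.

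The pairing of replicates was checked from the data. After group means were removed, libraries of the same batch label had a median correlation of 0.539 in MCF7, 0.437 in MCF10A and 0.279 in MCF12A, against -0.246, -0.141 and -0.0649 for other pairs. In all, 128, 137 and 133 of 140 same-label pairs were above 0.1. The R2 of the first principal component on batch was 0.938, 0.917 and 0.968, and on group 0.0119, 0.0302 and 0.00565. The common dispersion of edgeR dropped from 0.0772 to 0.0215, from 0.0623 to 0.0206 and from 0.0381 to 0.0103 with the block. Results with the block are therefore given beside the planned ones wherever they differ. The p values of single genes measure the spread between these libraries. Camera with the fixed correlation sets the genes of a list against other genes, and its p does not measure that spread.

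As a self-test, counts were drawn at random from the fitted means, batch effects and spreads of the real libraries, with 200 genes changed, 50 per size of change. For the 7 bisphenols at 50 nM in MCF7 (14908 genes), the fit recovered 0% of genes changed 1.25-fold, 32% of those changed 1.5-fold, 72% of those changed 2-fold and 100% of those changed 4-fold. With the block it recovered 24%, 68%, 92% and 100%. For Stomp Aqua in MCF10A (14232 genes) the shares were 6%, 46%, 76% and 98%, or 28%, 84%, 96% and 100% with the block. For the 7 bisphenols at 50 nM in MCF12A (14093 genes) they were 20%, 60%, 84% and 98%, or 62%, 84%, 94% and 100% with the block. Unchanged genes called were 0, 0 and 1 without the block and 6, 3 and 9 with it. Each gene was drawn on its own, so the self-test held no correlation between genes, no batch split and no length trend. It does not show how many calls these give. A shift of 0.25 log2 put into the 40 estrogen induced genes of MCF7 was read back as a median of 0.24. Splits of the libraries, 16 or 21 per blocked count and 100 per list, 16 of them parting every batch, gave the values that other groupings reach. Tables and graphs were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Transcript usage was left out, because only sums per gene were tested, and no library was left out of the planned fit.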

Results

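The 120 libraries came from MCF7, MCF10A and MCF12A after 48 h with bisphenol A (BPA), mixtures of bisphenols, pendimethalin, Stomp Aqua or vehicle. The lines differed in the estrogen pathway. ESR1, which encodes estrogen receptor alpha, stood at 410 ± 96.3 CPM in MCF7, 1.21 ± 0.345 CPM in MCF10A and 2.42 ± 0.461 CPM in MCF12A (mean ± SD, n = 40 libraries each). GREB1, an estrogen induced coactivator of that receptor, stood at 551 ± 130, 12.7 ± 3.81 and 6.19 ± 1.14 CPM, and PGR, the progesterone receptor, at 79.8 ± 32.8, 0.0141 ± 0.0371 and 0.00597 ± 0.0152 CPM. KRT5, a basal keratin, was at 3773 ± 657 CPM in MCF10A and 4243 ± 1207 CPM in MCF12A and at 0.202 ± 0.534 CPM in MCF7. GATA3, a luminal transcription factor, was at 1341 ± 253 CPM in MCF7, 29 ± 6.45 CPM in MCF10A and 7.93 ± 1.17 CPM in MCF12A. Batch, and not exposure, parted the libraries of every line. All groups of a line share 5 control libraries and are not independent.

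In MCF7, the 7 bisphenols at 50 nM were accompanied by higher estrogen induced genes and lower estrogen repressed genes. The median of the 40 estrogen induced genes was 0.25 log2 above control, with 33 of 40 positive (camera, adjusted p = 4.8e-09, and adjusted p = 0.035 with an estimated correlation). The call was lost with the block and an estimated correlation (adjusted p = 0.11). The mean of that list was above its same-batch control in 5 of 5 batches, by 0.287 ± 0.0625 log2 (mean ± SD, n = 5). Adjusted over the list alone, 5 genes passed without the block: EGR3 (1.01 ± 0.25 log2), an immediate early transcription factor, SERPINA1 (0.72 ± 0.22), alpha-1 antitrypsin, PDZK1 (0.68 ± 0.19), a scaffold protein, GREB1 (0.65 ± 0.20) and RERG (0.40 ± 0.09), an estrogen regulated GTPase. Over all 14983 genes the count was 0 without the block. With the block, 14 genes of the list were higher and 1 lower over the list alone, among them PGR (0.84 ± 0.22) and the amino acid transporter SLC7A5 (0.66 ± 0.25). The 12 estrogen repressed genes were all below control, with a median of -0.33 log2 (adjusted p = 0.00014, and adjusted p = 0.71 with an estimated correlation). Of these, 6 were lower over the list alone with the block, led by TGFB2 (-1.23 ± 0.42), a growth factor, PSCA (-0.98 ± 0.23), a surface antigen, PIK3IP1 (-0.70 ± 0.27), an inhibitor of PI3 kinase, and CSTA (-0.54 ± 0.16), a protease inhibitor. No left-out library ended either call (adjusted p from 1.0e-11 to 0.00036 for induced and from 1.0e-05 to 0.0096 for repressed genes).

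The 7 bisphenols at 50 nM also gave the largest set of single genes in MCF7, but only with the block. Without it, 0 of 14983 genes were called (edgeR; 252 at unadjusted p < 0.05; DESeq2 called 4), and with it 17 were higher and 10 lower. SPINK4 (9:33218365-33248567, GRCh38), a secreted protease inhibitor, was 1.87 ± 0.39 log2 above control (adjusted p = 0.027; 1.11 ± 0.981 against 0.290 ± 0.348 CPM). SDK2 (17:73334384-73644089), a cell adhesion molecule, was 1.17 ± 0.20 log2 above it (adjusted p = 0.011; 10.9 ± 3.15 against 4.81 ± 1.61 CPM), and VCAN (5:83471465-83582303), a matrix proteoglycan, 1.05 ± 0.18 (adjusted p = 0.011; 3.79 ± 1.23 against 1.89 ± 0.801 CPM). SLIT1 (10:96998038-97185920), an axon guidance ligand, fell by 1.02 ± 0.20 log2 (adjusted p = 0.025; 4.99 ± 4.33 against 9.10 ± 6.03 CPM). BPIFB1 (20:33273480-33309878), a secreted lipid binding protein, fell by 0.92 ± 0.19 (adjusted p = 0.027; 1.92 ± 0.783 against 3.54 ± 1.19 CPM) and LRATD1 (2:14632686-14650814), a cell shape gene, by 0.78 ± 0.16 (adjusted p = 0.027; 16.1 ± 12.3 against 26.5 ± 17.1 CPM). All 6 moved the same way in 5 of 5 batches, where the rule required at least 4, but batch 3 was split by exposure (below). Without batch 3, the blocked fit (edgeR) still called SDK2, BPIFB1 and LRATD1 (adjusted p = 0.034 each) but not SPINK4 (0.14), VCAN (0.059) or SLIT1 (0.062). The blocked count was 0 without batch 1 or batch 6, 2 without batch 5, 13 without batch 3 and 66 without batch 2, so the number of genes depended on single batches.

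Among the genes chosen beforehand, GREB1 (2:11482341-11642788) was at 736 ± 123 CPM under the 7 bisphenols at 50 nM in MCF7 against 471 ± 92.6 CPM in control. PGR (11:101029624-101130524) was at 112 ± 28.8 against 67.6 ± 32.2 CPM (0.73 ± 0.38 log2) and PDZK1 (1:145670852-145708148) at 16.6 ± 2.60 against 10.3 ± 1.86 CPM. TFF1 (21:42362282-42366594), a secreted trefoil peptide, was 0.43 ± 0.78 log2 above control, CXCL12 (10:44370165-44386493), a chemokine, 0.36 ± 0.32, MKI67 (10:128096659-128126385), a proliferation marker, 0.22 ± 0.29, and ESR1 (6:151656691-152129619) was -0.22 ± 0.22 log2 from it. None of the 7 passed over all genes. The proliferation list had a median of 0.14 log2 with 22 of 28 genes positive (adjusted p = 0.031, and adjusted p = 0.99 with an estimated correlation). With the block 4 of these genes passed over the list alone: CDK1 (0.27 ± 0.09), CCNA2 (0.26 ± 0.09), CDC6 (0.25 ± 0.08) and AURKA (0.25 ± 0.06), which drive replication and mitosis. That call was lost without control replicate 1 (0.47) or 2 (0.81) or treated replicate 3 (0.30), 5 (0.13) or 6 (0.41).

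Under the 6 alternatives without BPA at 50 nM, estrogen induced genes were also higher and estrogen repressed genes lower than control in MCF7. The estrogen induced list had a median of 0.21 log2 above control with 31 of 40 genes positive (adjusted p = 6.3e-08, and adjusted p = 0.040 with an estimated correlation). It was lost with the block and an estimated correlation (adjusted p = 0.11). Its mean was 0.249 ± 0.0961 log2 above the same-batch control, positive in 5 of 5 batches. Without the block PDZK1 (0.76 ± 0.19; 17.5 ± 6.38 CPM), SERPINA1 (0.74 ± 0.22; 12.7 ± 4.79 against 7.57 ± 1.42 CPM) and RERG (0.32 ± 0.09; 47.2 ± 4.87 against 37.9 ± 2.81 CPM) passed over the list alone. With the block 11 genes did, including PGR (0.65 ± 0.22), EGR3 (0.51 ± 0.17), CXCL12 (0.47 ± 0.15) and the ubiquitin ligase SIAH2 (0.44 ± 0.11). The 12 estrogen repressed genes were again all below control (median -0.42 log2, adjusted p = 0.00033, and adjusted p = 0.78 with an estimated correlation). TGFB2 (-1.17 ± 0.42), PSCA (-0.60 ± 0.23), CSTA (-0.49 ± 0.16) and EFEMP1 (-0.38 ± 0.14), a matrix protein, were lower over the list alone with the block. GREB1 was 0.42 ± 0.20, PGR 0.53 ± 0.38, TFF1 0.23 ± 0.78 and CXCL12 0.39 ± 0.32 log2 above control without the block, and MKI67 was -0.04 ± 0.29 and ESR1 -0.28 ± 0.22 log2 from it. The proliferation list had a median of 0.15 log2 with 27 of 28 genes positive (adjusted p = 6.0e-05, and adjusted p = 0.99 with an estimated correlation; 0.18 without control replicate 2). AGR2, a luminal protein disulfide isomerase, was 0.34 ± 0.11 log2 above control (338 ± 41.8 against 266 ± 21.1 CPM) and passed over its list alone.

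Over all genes in MCF7, the 6 alternatives gave a count of 0 (edgeR; 242 at unadjusted p < 0.05; DESeq2 called 4) and, with the block, 3 higher and 2 lower genes. SDK2 was 1.05 ± 0.20 log2 above control (adjusted p = 0.046; 10.1 ± 3.63 CPM). SNX24 (5:122843439-123029354), a sorting nexin, was 0.45 ± 0.08 (adjusted p = 0.032; 32.5 ± 2.13 against 23.9 ± 3.15 CPM) above control. TENT5C (1:117605934-117628372), a poly(A) polymerase, was 0.43 ± 0.08 above it (adjusted p = 0.046; 23.6 ± 3.86 against 17.6 ± 3.50 CPM). LIMCH1 (4:41359607-41700044), an actomyosin regulator, fell by 0.87 ± 0.17 (adjusted p = 0.046; 4.01 ± 2.05 against 8.28 ± 6.84 CPM), and ARNT2 (15:80404350-80597937), a partner of bHLH-PAS transcription factors, by 0.45 ± 0.08 (adjusted p = 0.032; 27.9 ± 2.61 against 38.7 ± 8.45 CPM). The blocked count was 0 without batch 1, 5 or 6 and 16 without batch 3.

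**Figure D1:**
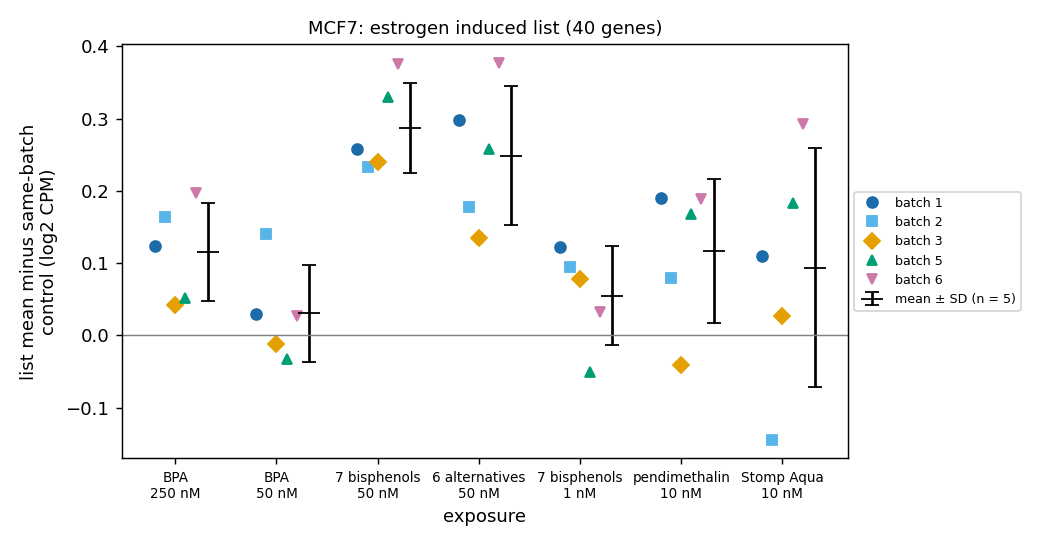
Mean log2 CPM of the 40 estrogen induced genes in each exposed MCF7 library minus the control library of the same batch. Symbols mark batches and bars the mean ± SD (n = 5).

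BPA alone at 50 nM left the estrogen induced genes of MCF7 near control. The list mean was 0.0305 ± 0.0668 log2 above the same-batch control. GREB1 was -0.02 ± 0.20 log2 from control (466 ± 89.9 CPM), PGR -0.10 ± 0.38, ESR1 -0.11 ± 0.22, TFF1 0.16 ± 0.78, PDZK1 0.14 ± 0.19, CXCL12 0.12 ± 0.32 and MKI67 0.01 ± 0.29. No list passed. The proliferation list passed with the block only (median 0.09 log2, adjusted p = 0.069 without and 0.00053 with it, and adjusted p = 0.65 with an estimated correlation). PPARG (-0.92 ± 0.32), THRA (-0.35 ± 0.11) and RXRA (-0.22 ± 0.07), which encode nuclear receptors, were lower over their list alone with the block. The count over all genes was 0 (edgeR; 218 at unadjusted p < 0.05; DESeq2 called 4).

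BPA alone at 250 nM in MCF7 gave estrogen list values between those of BPA at 50 nM and of the 2 mixtures at 50 nM. The estrogen repressed genes were all below control, with a median of -0.23 log2 (adjusted p = 0.034, and adjusted p = 0.99 with an estimated correlation), a call lost without control replicate 1 (0.15) or 2 (0.32) or BPA replicate 3 (0.28), 5 (0.058) or 6 (0.12). The estrogen induced list had a median of 0.09 log2 with 28 of 40 genes positive (adjusted p = 0.068; 0.030 with the block, and 0.66 with the block and an estimated correlation). Its mean was above the same-batch control in 5 of 5 batches, by 0.116 ± 0.0677 log2. The list test passed without control replicate 3 (0.0030) or BPA replicate 5 (0.011) or 6 (0.024). With the block and over the lists alone, PKIB (0.34 ± 0.10; 206 ± 61.3 against 162 ± 49.0 CPM), a kinase inhibitor, and RERG (0.29 ± 0.08; 46.5 ± 2.66 CPM) were higher and PSCA (-0.70 ± 0.23; 13.3 ± 3.87 against 21.7 ± 5.80 CPM) was lower. GREB1 was 0.23 ± 0.20 log2 above control (550 ± 32.6 CPM), PGR 0.35 ± 0.38, TFF1 0.36 ± 0.78, PDZK1 0.15 ± 0.19 and CXCL12 0.19 ± 0.32, and MKI67 was -0.12 ± 0.29 and ESR1 -0.11 ± 0.22 log2 from it. No gene passed over all genes (edgeR count 0; 241 at unadjusted p < 0.05; DESeq2 called 4; 0 with the block). The proliferation list passed with the block only (0.053 without and 0.00091 with it, and adjusted p = 0.65 with an estimated correlation). Mitochondrial encoded genes were below control (median -0.27 log2, adjusted p = 0.0019, and adjusted p = 0.99 with an estimated correlation). This was not so without control replicate 2 (0.076) or BPA replicate 2 (0.36) or 3 (0.23).

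At the labelled 50 nM in MCF7, the mixtures stood above BPA for the estrogen induced genes. The 7 bisphenols were listed with 50 nM of BPA and 50 nM of the alternatives, so their dose is not matched to that of BPA alone. The 7 bisphenols had a list median 0.22 log2 above that of BPA with 36 of 40 genes positive (adjusted p = 2.1e-17; 0.00012 with an estimated correlation), and the 6 alternatives 0.17 log2 with 35 of 40 positive (adjusted p = 9.9e-09; 0.0077 with an estimated correlation). Both calls held with the block and an estimated correlation (0.0013 and 0.027). Of the 16 splits that part every batch, 2 gave as small a camera p without the block for the 6 alternatives (real 2.14e-10, other 9.38e-14). For the 7 bisphenols 1 did, the real one. For the 6 alternatives minus BPA, the difference was 0.44 log2 for GREB1 (95% interval 0.03 to 0.84), 0.63 for PGR (-0.15 to 1.41) and 0.62 for PDZK1 (0.23 to 1.01). It was 0.07 for TFF1 (-1.51 to 1.65), 0.27 for CXCL12 (-0.38 to 0.93), -0.05 for MKI67 (-0.64 to 0.55) and -0.17 for ESR1 (-0.61 to 0.28). For the 7 bisphenols minus BPA it was 0.66 for GREB1 (0.25 to 1.07), 0.83 for PGR (0.05 to 1.61), 0.54 for PDZK1 (0.15 to 0.94), 0.27 for TFF1, 0.24 for CXCL12, 0.21 for MKI67 and -0.11 for ESR1. Estrogen repressed genes were lower under both mixtures than under BPA (medians -0.17 and -0.16 log2, adjusted p = 0.00035 and 0.043; 0.51 and 0.86 with an estimated correlation). The first call was lost without BPA replicate 1 (0.066) and the second without BPA replicate 1 (0.38) or 2 (0.44) or mixture replicate 3 (0.15), 5 (0.21) or 6 (0.24).

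Single genes parted the mixtures from BPA at 50 nM in MCF7 with the block only. SDK2 was 1.32 ± 0.21 log2 higher under the 7 bisphenols (adjusted p = 0.0054) and 1.19 ± 0.21 higher under the 6 alternatives (adjusted p = 0.030) than under BPA (4.28 ± 1.07 CPM). TRPV3 (17:3510502-3557995), a cation channel, was 0.74 ± 0.14 log2 higher (adjusted p = 0.032; 3.89 ± 0.502 against 2.33 ± 0.422 CPM) and BPIFB1 1.14 ± 0.19 log2 lower (adjusted p = 0.0076; 1.92 ± 0.783 against 4.09 ± 1.03 CPM) under the 7 bisphenols. Adjusted over the list alone and without the block, EGR3 (0.83 ± 0.25), SERPINA1 (0.67 ± 0.22), GREB1 and CELSR2 (0.52 ± 0.16; 1013 ± 70.9 against 708 ± 56.1 CPM), an adhesion receptor, were higher under the 7 bisphenols. CSTA was lower under both mixtures (-0.72 ± 0.20 and -0.64 ± 0.20). With the block 7 estrogen induced genes passed for the 6 alternatives, among them HEY2 (0.57 ± 0.12), a Notch target, and the receptor kinase RET (0.42 ± 0.10). Over all genes the counts without the block were 0 and 0 (edgeR; 129 and 185 at unadjusted p < 0.05; DESeq2 called 1 and 0) and with it 3 and 1. The 3 became 0 without batch 1 or 6, and the 1 became 0 without batch 1, 2, 5 or 6 and 4 without batch 3. The 95% interval of the difference between the 6 alternatives and BPA lay within 1 log2 of 0 for 83.4% of genes in MCF7, 86.3% in MCF10A and 89.5% in MCF12A. A p that misses the threshold does not show that compounds act alike. Mitochondrial encoded genes were higher under both mixtures than under BPA (medians 0.34 and 0.44 log2, adjusted p = 3.6e-06 and 5.1e-06; 0.86 for both with an estimated correlation), not so without BPA replicate 2 (0.27 in both) or, for the 7 bisphenols, mixture replicate 1 (0.082).

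Between the doses of BPA in MCF7, the estrogen induced list stood 0.07 log2 higher at 250 nM than at 50 nM, with 35 of 40 genes positive (adjusted p = 0.00030, and adjusted p = 0.19 with an estimated correlation; 0.083 without replicate 6 of BPA at 50 nM). GREB1 was 0.24 ± 0.20 and PGR 0.45 ± 0.38 log2 higher at 250 nM. The basal markers had a median of -0.21 log2 (adjusted p = 0.036, and adjusted p = 0.15 with an estimated correlation). Values ran from 0.0081 to 0.33 when single libraries were left out. The call was lost without replicate 1 (0.13), 2 (0.064) or 3 (0.19) at 250 nM or 1 (0.061), 5 (0.33) or 6 (0.24) at 50 nM. The count was 0 (edgeR; 62 at unadjusted p < 0.05; DESeq2 called 0). With the block it was 1, OR1I1, an olfactory receptor gene (-1.50 ± 0.26 log2, adjusted p = 0.023), which lies under 1 CPM in both groups and was named only after its value was seen.

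The 7 bisphenols at 1 nM showed no estrogen response in MCF7 that passed its test in the planned fit. GREB1 was 0.11 ± 0.20, PGR 0.06 ± 0.38, TFF1 0.24 ± 0.78, PDZK1 0.14 ± 0.19, CXCL12 0.18 ± 0.32 and MKI67 0.09 ± 0.29 log2 above control and ESR1 -0.11 ± 0.22 from it. The estrogen induced list mean was 0.0552 ± 0.0680 log2 above the same-batch control. The list test of those genes passed without control replicate 3 (0.018) or treated replicate 6 (0.016). Estrogen repressed genes passed with the block only (0.20 without and 0.026 with it, and adjusted p = 0.65 with an estimated correlation). The mixture at 50 nM stood above 1 nM by a median of 0.19 log2 in 35 of 40 estrogen induced genes (adjusted p = 3.0e-11; 0.0021 with an estimated correlation, 0.010 with the block and an estimated correlation). RERG (0.34 ± 0.09) was higher and CSTA (-0.72 ± 0.20) lower at 50 nM over the list alone. GREB1 was 0.54 ± 0.20, PGR 0.67 ± 0.38 and PDZK1 0.54 ± 0.19 log2 higher. Repressed genes had a median of -0.20 log2 (adjusted p = 0.00042, and adjusted p = 0.51 with an estimated correlation; 0.051 without replicate 2 at 1 nM). The proliferation list had a median of 0.09 log2 against control at 1 nM with 27 of 28 genes positive (adjusted p = 0.00096, and adjusted p = 0.99 with an estimated correlation). It was lost without control replicate 1 (0.38) or 2 (0.86) or treated replicate 3 (0.17), 5 (0.089) or 6 (0.21). Counts were 0 against control and 0 between doses (edgeR; 50 and 104 at unadjusted p < 0.05; DESeq2 called 3 and 0).

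Pendimethalin at 10 nM in MCF7 was accompanied by a small excess of estrogen induced genes, with 31 of 40 positive and a median of 0.10 log2 (adjusted p = 0.00033, and adjusted p = 0.49 with an estimated correlation; 0.13 without control replicate 6 and 0.078 without treated replicate 5). PDZK1 was 0.45 ± 0.19 log2 above control (14.1 ± 2.05 CPM), GREB1 0.20 ± 0.20, PGR 0.24 ± 0.38, TFF1 0.03 ± 0.78, CXCL12 0.24 ± 0.32 and MKI67 0.04 ± 0.29, and ESR1 was -0.03 ± 0.22 log2 from it. COL3A1, a fibrillar collagen, was 0.33 ± 0.09 log2 lower over its list alone with the block. All 28 proliferation genes were positive (median 0.09 log2, adjusted p = 0.0034; 0.99 with an estimated correlation), lost without control replicate 1 (0.60) or 2 (0.99) or treated replicate 5 (0.54) or 6 (0.73). The interferon list (median 0.19 log2, adjusted p = 0.016; 0.78 with an estimated correlation), basal markers (-0.30, 0.019; 0.23) and mitochondrial encoded genes (0.45, 0.024; 0.99) also passed with the fixed correlation. Interferon calls were lost without control replicate 3 (0.37), 5 (0.070) or 6 (0.16) or treated replicate 2 (0.14), 5 (0.13) or 6 (0.80). Basal marker calls were lost without control replicate 5 (0.21) or 6 (0.13) or treated replicate 2 (0.20) or 6 (0.062), and mitochondrial calls without control replicate 3 (0.33), 5 (0.63) or 6 (0.20) or treated replicate 1 (0.70), 2 (0.23), 5 (0.050) or 6 (0.21). Estrogen repressed genes passed with the block only (0.098 without and 0.0082 with it, and adjusted p = 0.60 with the block and an estimated correlation). The count over all genes was 0 (edgeR; 58 at unadjusted p < 0.05; DESeq2 called 3).

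Stomp Aqua at 10 nM of pendimethalin in MCF7 gave PDZK1 at 15.8 ± 2.83 CPM, 0.62 ± 0.19 log2 above control, and this gene passed over the list alone with the block together with FKBP4 (0.33 ± 0.09), an HSP90 co-chaperone, and PKIB (0.32 ± 0.10). GREB1 was 0.11 ± 0.20, TFF1 0.17 ± 0.78 and CXCL12 0.25 ± 0.32 log2 above control, and PGR was -0.15 ± 0.38, MKI67 -0.10 ± 0.29 and ESR1 -0.29 ± 0.22 log2 from it. The proliferation list had a median of 0.13 log2 with 24 of 28 genes positive (adjusted p = 0.019, and adjusted p = 0.99 with an estimated correlation). With the block 8 genes passed over the list alone, led by BIRC5 (0.36 ± 0.10), AURKB (0.34 ± 0.12) and CDC20 (0.33 ± 0.10), which act in mitosis. Oxidative stress genes passed with the block only (median 0.20 log2, adjusted p = 0.021, against 0.082 without it; 0.65 with the block and an estimated correlation). The leading genes were OSGIN1 (0.57 ± 0.19), PRDX1 (0.34 ± 0.09), NQO1 (0.30 ± 0.09) and TXN (0.27 ± 0.10), which limit oxidant damage. The proliferation call was lost without control replicate 1 (0.21) or 2 (0.44) or treated replicate 3 (0.090), 5 (0.082) or 6 (0.33). The estrogen induced list, at 0.28, passed without treated replicate 2 (0.0040). Against pendimethalin alone, mitochondrial encoded genes were lower under Stomp Aqua (median -0.49 log2, adjusted p = 0.036, and adjusted p = 0.99 with an estimated correlation). That call was lost without pendimethalin replicate 1 (0.32), 2 (0.086), 5 (0.086) or 6 (0.14) or Stomp Aqua replicate 2 (0.071) or 3 (0.63). Counts were 0 against control and 0 against pendimethalin (edgeR; 819 and 489 at unadjusted p < 0.05; DESeq2 called 3 and 0).

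**Figure D2:**
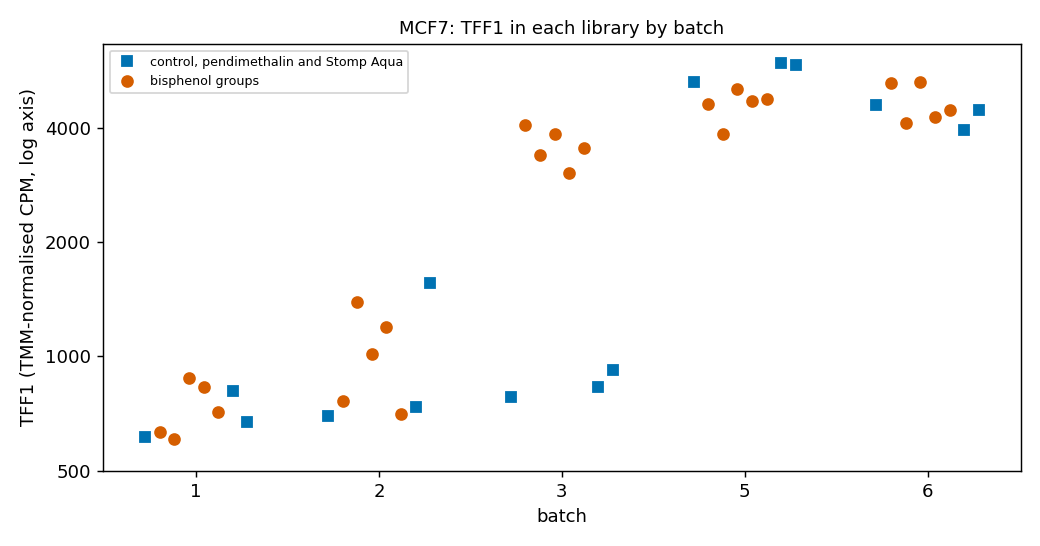
TFF1 in each of the 40 MCF7 libraries by batch (TMM-normalised CPM, log axis). Circles are the bisphenol groups and squares the control, pendimethalin and Stomp Aqua groups.

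In MCF10A, Stomp Aqua was accompanied by higher inflammatory cytokine genes, with 11 of 12 positive and a median of 0.65 log2 (adjusted p = 6.2e-05, and adjusted p = 0.91 with an estimated correlation; 0.051 without control replicate 1). With the block 11 of the 12 passed over the list alone, among them IL6 (2.26 ± 0.75 log2; 0.336 ± 0.455 against 0.0622 ± 0.0415 CPM) and CXCL8 (1.10 ± 0.31; 25.9 ± 10.4 against 13.7 ± 9.88 CPM). CXCL1 (1.06 ± 0.39), CXCL3 (0.94 ± 0.26) and CXCL2 (0.79 ± 0.31) followed, and all 5 are secreted cytokines or chemokines. Among single genes, NFKBIZ (3:101827991-101861022), a nuclear inhibitor of kappaB, was 1.19 ± 0.22 log2 above control (adjusted p = 0.044; 22.7 ± 11.8 against 10.1 ± 4.84 CPM). IL7R (5:35852695-35879603), a cytokine receptor, was 1.16 ± 0.26 (adjusted p = 0.048; 2.71 ± 1.53 against 1.30 ± 0.876 CPM) above control. TNFAIP3 (6:137867188-137883312), a ubiquitin editing brake on NF-kappaB, was 0.95 ± 0.17 above it (adjusted p = 0.044; 42.9 ± 9.43 against 25 ± 12.5 CPM). CAMK2B (7:44217150-44334577), a calcium dependent kinase, fell by 0.94 ± 0.21 (adjusted p = 0.048; 163 ± 110 against 302 ± 194 CPM, lower in 4 of 5 batches). DBP (19:48630030-48637438), a circadian transcription factor, fell by 0.80 ± 0.18 (adjusted p = 0.048) and ADAT3 (19:1905378-1913447), a tRNA deaminase subunit, by 0.57 ± 0.12 (adjusted p = 0.048). These calls came from the block, which gave 20 higher and 9 lower genes, against 0 without it (edgeR; 1220 at unadjusted p < 0.05; DESeq2 called 3). The blocked count was 0 without batch 1, 3 or 5, 148 without batch 2 and 434 without batch 6, and 0 without control replicate 6 alone, and the list mean was above the same-batch control in 4 of 5 batches (0.746 ± 0.802 log2, -0.344 to 1.76). With the block, 6 of 21 splits, the real one included and all among the 16 that part every batch, reached 29 genes (highest other 897). For the list test without the block, 13 of 100 splits and 3 of the 16 gave as small a p. Without the doubted libraries, a fit chosen after the results, this list passed under every exposure with the fixed correlation and none with an estimated one.

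**Figure D3:**
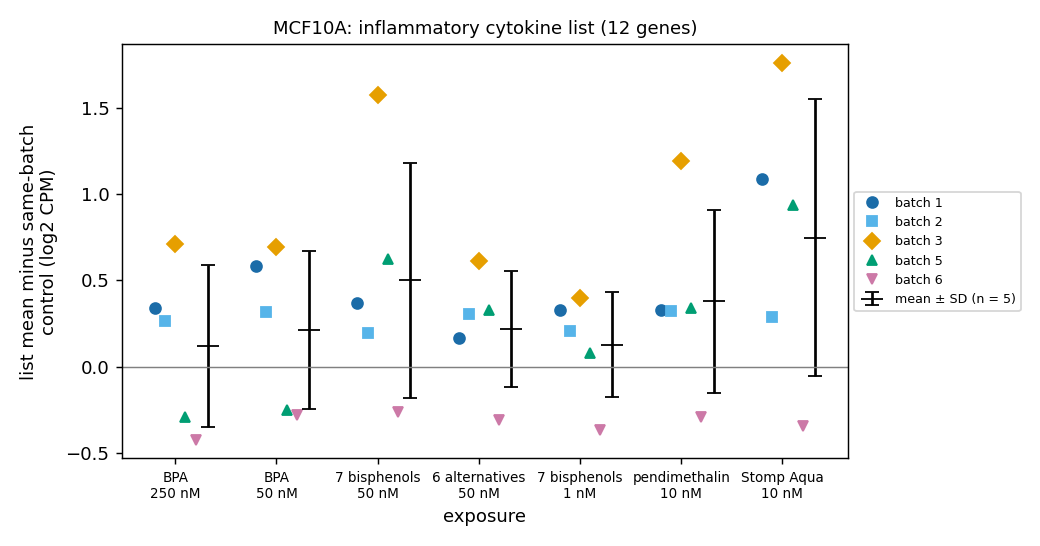
Mean log2 CPM of the 12 inflammatory cytokine genes in each exposed MCF10A library minus the control library of the same batch. Symbols mark batches and bars the mean ± SD (n = 5).

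Other lists also parted Stomp Aqua from control in MCF10A. The p53 response genes, which govern arrest and cell death, had a median of -0.23 log2 with 1 of 12 positive (adjusted p = 0.0036, and adjusted p = 0.71 with an estimated correlation). PHLDA3 (-0.47 ± 0.14), FDXR (-0.45 ± 0.14) and BAX (-0.38 ± 0.14) were among 9 lower over the list alone with the block. No left-out library ended that call (0.0022 to 0.035). Cholesterol synthesis genes had a median of 0.23 log2 (adjusted p = 0.019, and adjusted p = 0.99 with an estimated correlation), led by HMGCS1 (0.65 ± 0.19 with the block; 258 ± 138 against 170 ± 91.8 CPM), an early enzyme of the pathway. That call was lost without control replicate 2 (0.23) or 5 (0.17) or treated replicate 3 (0.20). LAMC2, a laminin chain, was 0.58 ± 0.18 log2 above control (953 ± 229 against 640 ± 216 CPM) and passed over its list alone without the block. RIGI (0.48 ± 0.11), OAS2 (0.46 ± 0.16) and STAT1 (0.31 ± 0.08), interferon response genes, were higher over their list alone with the block, and GREB1 was lower (-0.65 ± 0.17). Proliferation genes (median 0.38 log2) and unfolded protein response genes (-0.30) passed with the block only (0.066 and 0.20 without, 5.5e-07 and 0.031 with it; 0.65 and 0.69 with an estimated correlation). Against pendimethalin, inflammatory genes were higher under Stomp Aqua in 12 of 12 cases (median 0.40 log2, adjusted p = 8.3e-05, and adjusted p = 0.86 with an estimated correlation; 0.36 without pendimethalin replicate 1 and 0.18 without Stomp Aqua replicate 5).

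Proliferation and cholesterol genes also stood higher under Stomp Aqua than under pendimethalin in MCF10A (medians 0.26 and 0.14 log2, adjusted p = 0.038 and 0.0062; 0.99 and 0.98 with an estimated correlation). The proliferation call was lost without pendimethalin replicate 2 (0.47), 5 (0.080) or 6 (0.21) or Stomp Aqua replicate 1 (0.79), 3 (0.77) or 5 (0.34). The cholesterol call was lost without pendimethalin replicate 2 (0.48) or 5 (0.080) or Stomp Aqua replicate 1 (0.093), 3 (0.54) or 5 (0.056). The count was 0 (edgeR; 82 at unadjusted p < 0.05; DESeq2 called 4), and DSG3, a desmosomal cadherin, was 0.30 ± 0.10 log2 lower over its list alone with the block.

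Mitochondrial encoded genes, which code for subunits of the respiratory chain, were above control in MCF10A under all 7 exposures. The medians were 0.84 log2 for BPA at 250 nM (adjusted p = 0.0045), 1.18 for BPA at 50 nM (0.00095), 0.19 for the 7 bisphenols at 50 nM (0.047) and 1.02 for the 6 alternatives (8.3e-05). They were 1.5 for the 7 bisphenols at 1 nM (6.2e-10), 0.96 for pendimethalin (2.6e-05) and 0.63 for Stomp Aqua (0.0015). With an estimated correlation adjusted p was 0.78 at 1 nM and 0.99 elsewhere. MT-ND4 was 1.59 ± 0.81 and MT-CYB 1.56 ± 0.74 log2 above control under the 7 bisphenols at 1 nM. The share of mitochondrial reads was 0.583 ± 0.620% in control and 0.678% to 1.60% on average in the exposed groups, and the 5 control libraries are common to all 7 results. Control replicate 2 ended most of these calls when left out: adjusted p was then 0.41, 0.26, 0.73, 0.12, 0.066 and 0.28 in the order above without the 1 nM mixture, where no library ended the call. BPA at 250 nM also lost it without control replicate 5 (0.062) or BPA replicate 1 (0.35) or 3 (0.058). BPA at 50 nM lost it without BPA replicate 1 (0.12) or 2 (0.068), and the 7 bisphenols at 50 nM without control replicate 5 (0.20) or treated replicate 1 (0.23), 2 (0.083) or 5 (0.063).

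The 7 bisphenols at 50 nM in MCF10A had lower p53 response genes (median -0.16 log2, adjusted p = 0.022, and adjusted p = 0.78 with an estimated correlation) and higher inflammatory genes (0.38, 0.024; 0.99). With the block and over the lists alone, FDXR (-0.39 ± 0.13), GADD45A (-0.30 ± 0.11), TP53I3 (-0.24 ± 0.07) and CDKN1A (-0.18 ± 0.07), which act in the p53 pathway, were lower. IL6 (2.17 ± 0.76), TNFAIP3 (0.67 ± 0.17), IL1A (0.43 ± 0.15) and ICAM1 (0.34 ± 0.10) were higher. The p53 call was lost without control replicate 3 (0.068), 5 (0.065) or 6 (0.055) or treated replicate 1 (0.054), and the inflammatory call without control replicate 1 (0.48), 2 (0.12) or 3 (0.28) or treated replicate 3 (0.13), 5 (0.26) or 6 (0.056). Pendimethalin also had lower p53 response genes (median -0.21 log2, adjusted p = 0.021, and adjusted p = 0.78 with an estimated correlation), with FDXR at -0.53 ± 0.17 log2 past the threshold over the list alone without the block. That call was lost without control replicate 3 (0.061), 5 (0.051) or 6 (0.060) or pendimethalin replicate 1 (0.13). The 7 bisphenols at 1 nM had lower luminal markers (median -0.22 log2, adjusted p = 0.045, and adjusted p = 0.79 with an estimated correlation) with the keratin KRT8 at -0.29 ± 0.09. The luminal call was lost without control replicate 1 (0.068) or 6 (0.58) or treated replicate 1 (0.095), 2 (0.061) or 3 (0.076). The block added calls for proliferation (0.00083) and cholesterol synthesis (0.014) under the 7 bisphenols at 50 nM, p53 under the 6 alternatives (0.041) and the 7 bisphenols at 1 nM (0.032), and proliferation (0.049), unfolded protein response (0.016), inflammatory (0.014) and luminal genes (0.040) under pendimethalin. With the block and an estimated correlation the smallest adjusted p of these was 0.645.

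Single genes in MCF10A gave a count of 0 in the 6 other comparisons with control, with or without the block. Without the block edgeR had 1043, 1209, 1180, 1137, 1256 and 1253 genes at unadjusted p < 0.05 for BPA at 250 nM and 50 nM, the 7 bisphenols at 50 nM, the 6 alternatives, the 7 bisphenols at 1 nM and pendimethalin. DESeq2 called 1, 2, 5, 2, 2 and 3. TNFAIP3 was 0.54 ± 0.17 log2 above control under BPA at 50 nM over its list alone with the block, and TXN, a thioredoxin, was 0.72 ± 0.23 log2 below control without it. Left-out libraries changed the count from 0 to 1 without control replicate 2 (BPA at 50 nM, the 7 bisphenols at 50 nM, pendimethalin and Stomp Aqua) or 3 (pendimethalin). The 6 alternatives and BPA at 50 nM did not part in any list (edgeR count 0; 46 at unadjusted p < 0.05; DESeq2 called 0).

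In MCF12A, mitochondrial encoded genes were lower under the 7 bisphenols at 1 nM, with a median of -1.32 log2 and 0 of 13 positive (adjusted p = 4.6e-19, and adjusted p = 0.50 with an estimated correlation). All 13 passed over the list alone without the block, led by MT-ND5 (-1.44 ± 0.62), MT-ND4L (-1.42 ± 0.64) and MT-ATP8 (-1.39 ± 0.61), and 0 with it. No left-out library ended the list call (1.3e-25 to 2.7e-07), and the direction was opposite to that in MCF10A at the same dose. The 6 alternatives had a median of -0.53 log2 for these genes (adjusted p = 0.019, and adjusted p = 0.99 with an estimated correlation; 0.062 with the block). This call was lost without control replicate 1 (0.30), 2 (0.33), 3 (0.70) or 6 (0.061) or treated replicate 3 (0.79) or 5 (0.32).

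Stomp Aqua in MCF12A was accompanied by higher oxidative stress genes (median 0.12 log2, 11 of 12 positive, adjusted p = 0.0026, and adjusted p = 0.78 with an estimated correlation). Genes of the unfolded protein and integrated stress response were lower (median -0.28 log2, adjusted p = 0.046, and adjusted p = 0.99 with an estimated correlation). With the block and over the lists alone, GCLM (0.19 ± 0.05), a subunit of the enzyme that starts glutathione synthesis, was higher. CHAC1 (-2.65 ± 0.62; 2.08 ± 1.92 against 12.3 ± 11.6 CPM), DDIT3 (-0.79 ± 0.27), ASNS (-0.79 ± 0.30) and SESN2 (-0.61 ± 0.17), targets of the integrated stress response, were among 8 lower. The oxidative call was lost without control replicate 2 (0.23) or treated replicate 1 (0.23), and the stress response call without control replicate 1 (0.16), 5 (0.74) or 6 (0.16) or treated replicate 2 (0.52) or 3 (0.31). Against pendimethalin the oxidative stress list had a median of 0.08 log2 (adjusted p = 0.036, and adjusted p = 0.86 with an estimated correlation). It was lost without pendimethalin replicate 1 (0.058), 2 (0.30) or 6 (0.10) or Stomp Aqua replicate 1 (0.61), 3 (0.064), 5 (0.092) or 6 (0.13). The unfolded protein list passed with the block only (0.093 without and 0.00087 with it, and adjusted p = 0.46 with the block and an estimated correlation).

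Inflammatory genes in MCF12A were slightly above control under the 6 alternatives (median 0.11 log2, adjusted p = 0.026, and adjusted p = 0.99 with an estimated correlation) and pendimethalin (0.06, 0.038; 0.99). The first was lost without control replicate 1 (0.12), 2 (0.33) or 3 (0.51) or treated replicate 5 (0.22) or 6 (0.20), and the second without control replicate 1 (0.12), 2 (0.37) or 3 (0.72) or treated replicate 1 (0.089), 3 (0.18), 5 (0.081) or 6 (0.079). GREB1 was -0.09 ± 0.17 log2 from control under the 7 bisphenols at 1 nM and -0.10 ± 0.17 under Stomp Aqua. No list passed for BPA at either dose or for the 7 bisphenols at 50 nM, where proliferation (0.0033) and unfolded protein genes (0.049) passed with the block only. The block also added cholesterol synthesis (0.0049) and basal genes (0.032) under the 6 alternatives, the same lists at 1 nM (0.016 and 0.012), and proliferation (0.00031) and inflammatory genes (0.029) under Stomp Aqua. The smallest adjusted p of these 8 with the block and an estimated correlation was 0.545. Counts were 0 in all 7 comparisons with control with and without the block (edgeR; 77, 113, 89, 110, 255, 58 and 91 at unadjusted p < 0.05 in the order of the labels; DESeq2 called 3, 5, 4, 3, 3, 3 and 2). They were also 0 for the 6 alternatives against BPA and for Stomp Aqua against pendimethalin (58 and 102; DESeq2 called 2 and 1).

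The responses of MCF7 were compared with the mean response of MCF10A and MCF12A. For the 6 alternatives, estrogen induced genes responded more in MCF7 (median 0.17 log2, adjusted p = 0.00068; 0.092 with an estimated correlation, 0.044 with the block and an estimated correlation) and estrogen repressed genes moved lower there than in the other lines (-0.41, 0.0067; 0.59; 0.0078). CTSD, a lysosomal protease (0.44 ± 0.10), and SIAH2 (0.35 ± 0.09) responded more, and TGFB2 (-1.14 ± 0.24) and EFEMP1 (-0.51 ± 0.15) moved lower, over the list alone with the block. ITGB6 (2:160099666-160200313), an integrin chain, differed by -1.56 ± 0.18 log2 (adjusted p = 0.0038 with the block; 6.22 ± 2.32 against 17 ± 7.78 CPM in MCF7). NT5E (6:85449584-85495791), an ectonucleotidase, differed by -1.11 ± 0.15 (adjusted p = 0.0081; 2.40 ± 0.850 against 4.94 ± 2.33 CPM). There were 0 calls without the block (edgeR; 256 at unadjusted p < 0.05; DESeq2 called 2; 1 without MCF7 control replicate 3). For BPA at 250 nM, repressed genes (median -0.26 log2, adjusted p = 0.035; 0.66 with an estimated correlation) and mitochondrial encoded genes (-0.53, 0.00065; 0.70) moved lower in MCF7 than in the other lines. The only gene called there without the block was HSFX1 (X:149774068-149776867), a heat shock factor gene at -3.55 ± 0.57 log2 (adjusted p = 0.027; 0.77 with the block), 1 of a near identical pair with HSFX2, so its reads cannot be placed with certainty. That count was 0 without MCF7 control replicate 1, 2 or 3, MCF7 BPA replicate 2, 3, 5 or 6, MCF10A control replicate 2 or 3, MCF10A BPA replicate 1, 5 or 6, MCF12A control replicate 1, 3 or 5, or MCF12A BPA replicate 1, 2 or 3. For pendimethalin the estrogen induced list responded more in MCF7 (0.11 log2, adjusted p = 0.017; 0.26 with an estimated correlation), with a count of 0 (edgeR; 169 at unadjusted p < 0.05; DESeq2 called 4). Line and medium were confounded in these 3 comparisons.

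Lists that never passed against control covered receptors and other pathways. Steroid and nuclear receptors (12 to 15 measured) had medians from -0.20 to 0.10 log2 and a smallest adjusted p of 0.187, and aryl hydrocarbon and xenobiotic genes (9 to 10) -0.24 to 0.17 and 0.150. Glucocorticoid and androgen response genes (9 to 10) had medians from -0.17 to 0.07 log2 and a smallest adjusted p of 0.0691, and mesenchymal and fibroblast markers (6 to 9) -0.29 to 0.20 and 0.375. Of the immune cell markers 3 were measured, with medians from -0.24 to 0.40 log2, and the list was not tested. The inflammatory list was not tested in MCF7, where 3 genes were measured.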

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

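Tests written only after the pattern had been seen were the 3 on MCF7 batch 3 and those on transcript length, genes with many reads and induction of MCF7-type transcripts. The rest were planned.

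In MCF7 batch 3, TFF1 and the first principal component parted the 8 libraries into 2 sets. TFF1 levels in this paragraph are CPM without TMM factors. TFF1 stood at 3526 ± 359 CPM in the 5 bisphenol libraries and at 853 ± 61.6 CPM in the control, pendimethalin and Stomp Aqua libraries, against 4490 and 5391 CPM in batch 5 and 773 and 728 CPM in batch 1. The 2 sets lay 37.6 apart on the first principal component, while the largest distance in another batch was 3.13, so a response to the bisphenols does not account for the split. Across genes, the difference between the sets had a Pearson r of 0.764 with the difference between batches 5 and 6 and batches 1 and 2, which is consistent with 2 cultures or harvests under 1 label. With batch 3 left out and the block kept, the smaller of the medians of the estrogen induced list under the 2 mixtures at 50 nM was 0.263 log2, so the split does not account for that result.

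MCF10A control replicate 6 and MCF7 Stomp Aqua replicate 2 stood apart from their batches, with a residual spread 2.87 and 1.79 times the median of their line. The smaller of their 2 differences in median log2 ratio between genes under 500 bp and genes over 4000 bp was 1.57, against 0.713 at most in any other library, which may point to a loss that depends on transcript length. The larger share, of MCF7 transcripts in the first library or MCF10A transcripts in the second, was 0.0978%, too small to account for it. Transcripts of MCF12A were not looked for. The higher rank of the 2 totals within their groups was 2 (1 is the fewest), which alone left the number of reads open. Over genes with at least 1000 reads in every library of the line, where sampling adds at most 0.0456 log2, their spreads were 0.773 and 0.570 log2. The smaller of the 2 ratios to the median of the line was 4.60, against 3.34 at most in another library, so fewer reads do not account for it.

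MCF7-type transcripts such as TFF1 were seen above 1 CPM in 6 of 80 libraries of MCF10A and MCF12A, 5 of them in batch 5. In these, other MCF7-only genes had a median of 1.19 times the share that TFF1 had (0.940 to 1.29), with a largest share of 0.190%, which is consistent with carry-over of MCF7 RNA or reads. Induction by an exposure does not account for it, because 2 of the 6 were control libraries.

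Of 128 checks for a library apart from its group, 6 were met, and 6.4 would be met by chance (about 1 in 20). Replicate 6 of MCF7 with BPA at 250 nM held 60521473 reads against 21266294 to 27024857 in its group (0.853 of the range). Replicate 1 of the same group had 3.01% mitochondrial reads against 0.220% to 0.839% (0.778). In MCF10A, replicate 1 of the 6 alternatives had 3.22% against 0.373% to 1.16% (0.725) and replicate 1 of Stomp Aqua 1.98% against 0.341% to 0.788% (0.726). In MCF12A, replicate 3 of the 7 bisphenols at 1 nM held 52102288 reads against 19593328 to 28044373 (0.740). The estrogen induced list had a median of 5.45 log2 CPM in replicate 2 of Stomp Aqua in MCF12A against 5.11 to 5.17 (0.837).

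Responses that differed between MCF7 and the other lines were HSFX1 for BPA at 250 nM (adjusted p = 0.0273, edgeR), a call lost with the block (0.765) and without many single libraries, and, with the block only, ITGB6 (0.00383) and NT5E (0.00813) for the 6 alternatives. Among lists (camera), they were the estrogen repressed (0.0347) and mitochondrial encoded genes (0.000651) for BPA at 250 nM, the estrogen induced (0.000680) and repressed genes (0.00673) for the 6 alternatives, and the estrogen induced genes for pendimethalin (0.0166). With an estimated correlation all 5 list calls were lost (adjusted p = 0.66, 0.70, 0.092, 0.59 and 0.26).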

How the results depend on the processing

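Alternatives that added to the block, left out the 2 doubted libraries or left out MCF7 batch 3 were chosen only after the results had been seen.

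The main limits were 5 shared controls per line and batch as the largest source of variation. Most gene calls needed the block, and most list calls the fixed correlation. The cause of the shifts below was not tested. Apart from the values given here and in the results, the block changed no other call.

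DESeq2 without the block called 4 genes in MCF7 for BPA at 250 nM, BPA at 50 nM, the 7 bisphenols at 50 nM and the 6 alternatives, and 3 for the 7 bisphenols at 1 nM, pendimethalin and Stomp Aqua. It called 1, 2, 5, 2, 2, 3 and 3 in MCF10A and 3, 5, 4, 3, 3, 3 and 2 in MCF12A in the same order, against 0 with edgeR. Between exposures it called 1 for the 7 bisphenols against BPA in MCF7, 4 for Stomp Aqua against pendimethalin in MCF10A, 2 for the 6 alternatives against BPA and 1 for Stomp Aqua against pendimethalin in MCF12A. For the line differences it called 3 for BPA at 250 nM, 2 for the 6 alternatives and 4 for pendimethalin. Without the low count filter, 1 gene was called in each of the 7 comparisons with control in MCF10A and 0 in the line difference for BPA at 250 nM. A fit of the 2 compared groups only called 1 for BPA at 250 nM in MCF12A. With single libraries left out, counts ran from 0 to 1 in MCF10A for BPA at 50 nM, the 7 bisphenols at 50 nM, pendimethalin and Stomp Aqua, and from 0 to 1 in the line differences for BPA at 250 nM and the 6 alternatives.

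With the block the counts were 27 for the 7 bisphenols at 50 nM, 5 for the 6 alternatives, 1 for BPA at 250 nM against 50 nM, 3 for the 7 bisphenols against BPA and 1 for the 6 alternatives against BPA in MCF7, 29 for Stomp Aqua in MCF10A, 2 for the line difference of the 6 alternatives and 0 for that of BPA at 250 nM. The 27 became 136 with DESeq2, 179 with the length trend, 90 without the doubted libraries, 13 without batch 3 and 0 to 66 with single batches left out. The 5 became 62 with DESeq2, 3 with RLE size factors, 0 without the filter, 0 with the length offset, 43 with the length trend, 20 without the doubted libraries, 16 without batch 3 and 0 to 16 with single batches left out. For BPA at 250 nM against 50 nM, the 1 became 0 without the filter, 0 with the length offset, 2 with the length trend, 0 without batch 3 and 0 to 0 with single batches left out. For the 7 bisphenols against BPA, the 3 became 13 with DESeq2, 15 with the length trend, 9 without the doubted libraries and 0 to 3 with single batches left out. For the 6 alternatives against BPA, the 1 became 20 with DESeq2, 0 with the length offset, 4 with the length trend, 2 without the doubted libraries, 4 without batch 3 and 0 to 4 with single batches left out. The 29 of Stomp Aqua in MCF10A became 938 with DESeq2, 2 with RLE size factors, 18 without the filter, 0 with the length offset, 117 with the length trend, 0 without the doubted libraries and 0 to 434 with single batches left out. The 2 of the line difference became 46 with DESeq2, 4 without the filter, 4 with the length offset, 12 without the doubted libraries and 0 to 5 with single batches left out.

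Of the list tests against control, 35 passed as planned, 2 with the estimated correlation, 58 with the block, 0 with the block and the estimated correlation and 65 with the block and the length trend. The estrogen induced list in MCF7 for BPA at 250 nM had an adjusted p of 0.0303 with the block, 0.0231 with the block and without the doubted libraries, 0.000659 without batch 3, 0.0474 with the length trend, 0.0480 without the block and the doubted libraries, and 0.00305 to 0.495 with single libraries left out. For BPA at 50 nM the direction that camera gave, from the mean statistic of the list against other genes and not from the median, was reversed from lower to higher without batch 3 (median 0.0152 log2, adjusted p = 0.621) and without control replicate 3 (0.0393 log2, 0.488) or 5 (-0.0196, 0.987) or BPA replicate 1 (-0.0221, 0.979), 5 (0.0152, 0.859) or 6 (0.0711, 0.732). The adjusted p ran from 0.488 to 0.987 over all left-out libraries. For the 7 bisphenols and the 6 alternatives at 50 nM it was 0.113 in both cases with the block and the estimated correlation. For the 7 bisphenols at 1 nM it ran from 0.0156 to 0.971 with single libraries left out. For pendimethalin it was 0.487 with the estimated correlation, 0.530 with the block and the estimated correlation, and 1.19e-05 to 0.133 with single libraries left out. For Stomp Aqua it was 7.74e-06 with the block and without the doubted libraries, 0.0137 without batch 3, 0.000261 with the length trend, 0.00215 without the block and the doubted libraries, and 0.00400 to 0.607 with single libraries left out. For BPA at 250 nM against 50 nM it was 0.186 with the estimated correlation, 0.303 with the block and the estimated correlation, and 7.52e-05 to 0.0829 with single libraries left out. For Stomp Aqua against pendimethalin it was reversed at 0.278 with the block and without the doubted libraries, at 0.775 with the length trend, at 0.603 without the block and the doubted libraries, and at 0.651 without Stomp Aqua replicate 2 (0.651 to 0.986 over all left-out libraries). The estrogen repressed list was at 0.713 and 0.782 with the estimated correlation for the 7 bisphenols and the 6 alternatives, and at 0.125 in both cases with the block and the estimated correlation.

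Other list calls were lost in fits chosen after the results. With the block and the length trend these were mitochondrial encoded genes for pendimethalin (0.0699) and for Stomp Aqua against pendimethalin (0.0696) and basal markers for BPA at 250 nM against 50 nM (0.0555) in MCF7, and luminal markers for the 7 bisphenols at 1 nM in MCF10A (0.109). The luminal call was also lost without the doubted libraries, with the block (0.265) and without it (0.564). Without the block and the doubted libraries, repressed genes for the 6 alternatives against BPA (0.0509) and mitochondrial genes for Stomp Aqua against pendimethalin (0.0606) in MCF7 and proliferation for Stomp Aqua against pendimethalin in MCF10A (0.0648) were lost. With the block and without MCF7 batch 3, mitochondrial genes for BPA at 250 nM (0.0642) and for Stomp Aqua against pendimethalin (0.0640) and basal markers for BPA at 250 nM against 50 nM (0.0862) were lost.

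The block also added list calls between exposures, given here with the adjusted p with the block and then with the block and the estimated correlation. They were repressed genes for BPA at 250 nM against 50 nM (0.00873, 0.459) and proliferation for the 6 alternatives against BPA (0.0300, 0.731) in MCF7, repressed and oxidative stress genes for Stomp Aqua against pendimethalin in MCF10A (0.0362, 0.368 for both), and inflammatory genes for the 6 alternatives against BPA (0.00234, 0.664) and proliferation for Stomp Aqua against pendimethalin (0.000467, 0.731) in MCF12A. In the line differences they were aryl hydrocarbon (0.0214, 0.116), oxidative stress (0.0402, 0.209) and basal genes (0.00991, 0.116) for BPA at 250 nM, proliferation (0.00456, 0.471) and oxidative stress (0.0284, 0.158) for the 6 alternatives, and repressed (0.000633, 0.116), oxidative stress (0.0179, 0.345), cholesterol (0.0214, 0.401), inflammatory (0.0296, 0.471) and basal genes (0.00959, 0.102) for pendimethalin.

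Single genes with a reversed direction were GREB1 for BPA at 50 nM (0.0389 log2), MKI67 (0.0671) for the 6 alternatives, PGR (0.0358) and MKI67 (0.0745) for Stomp Aqua and MKI67 (0.0418) for the 6 alternatives against BPA, all with the length offset, and MKI67 for BPA at 50 nM with DESeq2 (-0.00635), all in MCF7 and near 0.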

Other observations

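The split and relabelling tests below were planned before any result was seen, except that the number of relabellings of the line differences was raised after a first draw, and the genes in the next 2 paragraphs were chosen only after their values had been seen.

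With the block, further genes were called for the 7 bisphenols at 50 nM in MCF7. EGR3 (8:22687659-22693302, GRCh38) was 0.98 ± 0.17 log2 above control over all genes (adjusted p = 0.011, edgeR; 17.4 ± 3.14 against 8.65 ± 1.74 CPM), PRSS23, a secreted serine protease, 0.75 ± 0.15 (0.027; 631 ± 305 against 351 ± 124 CPM), FRK, a tyrosine kinase, 0.58 ± 0.11 (0.019), and PKIB 0.46 ± 0.10 (0.032). INHBB, a subunit of activin and inhibin (-0.40 ± 0.08, 0.027; 105 ± 23.5 against 139 ± 26.2 CPM), JUN, a subunit of AP-1 (-0.43 ± 0.09, 0.035; 41.0 ± 17.5 against 55 ± 22.8 CPM), FZD8, a Wnt receptor (-0.47 ± 0.10, 0.030; 11.5 ± 3.07 against 15.9 ± 3.46 CPM) and the uroplakin UPK2 (-0.72 ± 0.15, 0.032) fell. In MCF7 the enzyme genes ALDH3A1 (-0.95 ± 0.32), UGT1A6 (-0.78 ± 0.27) and NQO1 (-0.23 ± 0.09) and AHRR (-0.47 ± 0.13), a repressor of the aryl hydrocarbon receptor, were lower over their list alone under this mixture, and the cystine transporter SLC7A11 (0.72 ± 0.22) and GCLM (0.40 ± 0.12) were higher over theirs.

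In MCF10A under Stomp Aqua, the block called further genes (edgeR, adjusted p = 0.048 for each), picked here from a count that other splits also reached (29 genes, 6 of 21 splits). NFKB2, an NF-kappaB subunit, was 0.73 ± 0.16 log2 above control (37.6 ± 9.76 against 23.0 ± 5.96 CPM), ZC3H12A, an RNase that trims cytokine mRNA, 0.92 ± 0.20 (71.0 ± 45.9 against 36.9 ± 24.1 CPM), LIF, an IL6 family cytokine, 0.76 ± 0.16 (12.3 ± 5.45 against 7.16 ± 2.93 CPM), IL1A 0.67 ± 0.15 (78.1 ± 29 against 49.5 ± 17.8 CPM) and TNIP1, a partner of TNFAIP3, 0.58 ± 0.12. SERPINE1, the inhibitor of plasminogen activators, was 0.66 ± 0.13 log2 above control and the laminin chain LAMB3 0.47 ± 0.10, while HADHB (-0.32 ± 0.07) and AUH (-0.35 ± 0.07), mitochondrial enzymes that break down fatty and amino acids, fell. Without the 2 doubted libraries the median of the inflammatory list was 1.01 log2 in this comparison (camera, adjusted p = 3.4e-15; 0.18 with an estimated correlation), and it passed in all 7 comparisons with control in MCF10A (0.0059 for BPA at 250 nM, 0.0014 for BPA at 50 nM, 5.2e-13, 4.1e-05, 0.0068 and 1.2e-08 for the next 4). With an estimated correlation the adjusted p of these 6 inflammatory lists was 0.86, 0.78, 0.21, 0.55, 0.86 and 0.43, so all were lost.

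For the estrogen induced genes of MCF7, the list mean over the same-batch control was 0.117 ± 0.0996 log2 for pendimethalin and 0.0937 ± 0.165 for Stomp Aqua (bisphenols above). Against control with an estimated correlation, the list passed for the 7 bisphenols at 50 nM (adjusted p = 0.035) and the 6 alternatives (0.040), and it passed for neither with the block and the estimated correlation (0.113 in both cases). The labels left open whether 50 nM of the alternatives is the dose of each compound or of their sum. ESR1 is near absent in MCF10A and MCF12A, where no estrogen list passed against control.

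Grouping by chance was weighed by splits of the control and treated libraries. Because the libraries were paired by batch, the real split is comparable only with the 16 splits that part every batch, and 16 are too few for a share under 1 in 20. The other splits put both libraries of at least 1 batch into the same group. For the counts of 0 without the block, all 126 splits reach 0 by definition, so they test nothing. With the block, only the real split reached the 27 genes of the 7 bisphenols (1 of 21 splits, 16 of them parting every batch, highest other 0) and the 5 genes of the 6 alternatives (1 of 21, highest other 3). For BPA at 250 nM against 50 nM (1 gene, highest other 0), the 7 bisphenols against BPA (3 genes, highest other 0) and the 6 alternatives against BPA (1 gene, highest other 0), it was 1 of 16. In all 5 cases the splits were too few to tell. For Stomp Aqua in MCF10A, 6 of 21 splits reached the 29 genes, all 6 among those that part every batch, and the highest other called 897, which points to some structure among the samples that was not tested. For the line difference of the 6 alternatives with the block, 4 of 22 relabellings reached the 2 genes (highest other 5), so chance could not be excluded. For the line difference of BPA at 250 nM without the block, 1 of 22 reached the 1 gene, the real one (highest other 0). A first draw of 20 relabellings, seen before the number was raised to 22 so that a share under 0.05 could be reached, had 2 with 1 gene for BPA and 3 with 2 genes or more for the 6 alternatives. The outcome for BPA thus changed with the draw, and chance is not taken as excluded for it.

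For the estrogen induced list in MCF7 (camera without the block), 100 splits with the real one were drawn, among them the 16 that part every batch, so the test was too small to tell in every comparison. Splits with as small a p, of 100 and of the 16, were 2 and 1 for the 7 bisphenols at 50 nM (4.40e-11, smallest other 4.31e-12, or 8.50e-08 among the 16) and 1 and 1 for the 6 alternatives (7.69e-10, smallest other 1.07e-09). They were 4 and 2 for pendimethalin (1.10e-05, smallest other 1.29e-07), 14 and 4 for BPA at 250 nM (0.00867, smallest other 7.66e-06), 94 and 16 for BPA at 50 nM (0.901, smallest other 2.47e-05), 42 and 5 for the 7 bisphenols at 1 nM (0.107, smallest other 7.84e-09) and 32 and 8 for Stomp Aqua (0.0708, smallest other 1.90e-07). Between exposures they were 1 and 1 for the 7 bisphenols against BPA (1.54e-19, smallest other 1.69e-12), 1 and 1 for the 7 bisphenols at 50 nM against 1 nM (4.26e-13, smallest other 3.97e-11), and 2 and 2 for the 6 alternatives against BPA (2.14e-10, smallest other 9.38e-14). The inflammatory list under Stomp Aqua in MCF10A had 13 and 3 (1.31e-06, smallest other 5.10e-12).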
